A study of Mus musculus with 10 samples.

How the data were processed

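Gene expression was measured on 10 Affymetrix mouse 430A 2.0 arrays, each hybridised with total RNA of intestinal epithelial cells from C57BL/6 mice. The labels name 5 groups of 2 arrays: Lgr5-positive stem cells sorted by their green fluorescent protein (ISC), crypt secretory progenitors enriched by deleting Rbpj (Rbpj Sec-Pro) or by dibenzazepine, a Notch inhibitor (DBZ Sec-Pro), and crypt enterocyte progenitors (Ent-Pro) and villus enterocytes (ENT) from mice without Atoh1. Per the labels' protocols, crypts were released in 5 mM EDTA over 50 min and villi in 5 mM EDTA over 25 min, and RNA was extracted with Trizol. The labels do not say that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. In 1 of the 5 groups the 2 arrays differed by over 2 (log2) in a gene of the Y chromosome, so these at least hold RNA of different animals.

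The authors deposited log2 values for 22690 probe sets, ranging from 2.90 to 15.18. Per the submitters' processing notes, RMA and MAS5 were used, with no role or version given for either. Medians of the arrays lay between 6.83 and 6.98, so the deposited log2 values were used as they stood, with no further scaling. How firmly a difference can be stated is limited by the number of arrays.

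Probe sets were named through the platform annotation given with the values, with symbols updated by Entrez identifier. Of the probe sets, 20393 had 1 gene symbol, 691 had several and 1606 were unnamed here. Entrez identifiers of 20364 of the single-gene probe sets matched the reference gene table and 29 did not, and 0 symbols changed. Probe sets with several symbols or none were not used. The 64 control probe sets, 13 of which carry a gene symbol, were left out, a choice made after the values had been seen because some controls would otherwise have stood for their genes. For each gene the probe set with the highest mean over all arrays was used, which matters for the 4956 genes with more than 1. This left 12393 genes, with no filter on dim genes. Olfm4 and Muc2, which the rule for named genes lists, were not among the genes tested.

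All 10 arrays entered 1 linear model with 5 group means in limma (lmFit and eBayes), with 5 residual and 3.75 prior degrees of freedom. A gene was called past an adjusted p (Benjamini-Hochberg) of 0.05. Comparisons were Sec-Pro (the mean of both Sec-Pro groups) against Ent-Pro, Sec-Pro against ISC, Ent-Pro against ISC, ENT against Ent-Pro, and DBZ against Rbpj Sec-Pro. The calls of DBZ and of Rbpj Sec-Pro against Ent-Pro were overlapped, and the correlation of their log2 fold changes was set beside 100 simulations of unchanged groups. A gene within 1 (log2) of the absent control TrpnX on every array of a group is called near background there, and one within 0.1 of the array's highest value at the top of the scale, 2 bounds set after the data had been seen. Fold changes of named genes against such a group are given as at least N-fold, with a gene near background set to the absent control plus 1. Their log2 fold changes, ranks and p-values are those measured. On simulated data with 200 of 12393 genes changed, the test recovered 73% of changes of log2 1 and 92% of changes of log2 2 for Sec-Pro against Ent-Pro. These shares were 77% and 94% for Sec-Pro against ISC, 68% and 96% for Ent-Pro against ISC, 69% and 96% for ENT against Ent-Pro, and 72% and 93% for DBZ against Rbpj Sec-Pro. In the same order, 12, 9, 9, 11 and 7 unchanged genes were called. Noise was drawn separately for each gene, with no effect shared by the genes of an array. Far fewer genes changed than were called in the data, so these shares and counts need not hold there.

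There were 21 gene lists, of Paneth, goblet, enteroendocrine, tuft and stem cell markers, secretory regulators, Notch genes, Wnt targets, cell cycle, brush border, lipid absorption, transporter, enterocyte transcription factor, xenobiotic metabolism, chromatin, unfolded protein response and immediate-early genes, leukocyte, stromal and pancreatic acinar markers, and MHC class II genes. They held 427 genes, of which 356 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 105 tests, and again with an estimated correlation and with fry. At the preset correlation 60 tests passed, with an estimated correlation 0 passed, the smallest adjusted p being 0.176, and by fry, which asks only whether a list's genes move one way on balance, 58 passed. Median and mean of a list differed in sign in 4 of the tests, and median and direction of the camera test in 4.

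The genes to name were fixed by rule: the 8 largest changes per direction among called genes whose arrays did not overlap between the groups, up to 4 called members of each list (the 2 with the smallest p where fewer than 2 passed), and Atoh1, Rbpj, Lgr5, Hes1, Mki67, Lyz1, Chga, Fabp1 and Apoa1. The text prints the list members with the largest changes. Design, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were other ways to combine probe sets, filters on dim genes, other scalings, other variance settings, array weights, fold thresholds, a replicate block, fits on fewer groups or with the Sec-Pro arrays merged or split, and each array left out in turn. Leaving out the 2 arrays with low MHC class II genes was added after the data had been seen. With 1 array left out, the remaining array of that group was assumed to vary like the other groups. Software was R 4.3.3 with limma 3.58.1 and data.table in version 1.17.8, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.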

Results

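The data covered intestinal epithelium from stem cell to mature enterocyte: sorted stem cells (ISC), secretory progenitors of the crypt obtained in 2 ways (Rbpj Sec-Pro and DBZ Sec-Pro), enterocyte progenitors of Atoh1-null crypts (Ent-Pro) and enterocytes of Atoh1-null villi (ENT), each on 2 arrays. Across genes, arrays of the same group correlated with r from 0.982 to 0.995 and arrays of different groups with r from 0.886 to 0.980. Genes are not independent replicates. On the first principal component, which held 48.6% of the variance, ISC and ENT lay at opposite ends, and on the second, with 25.1%, the 4 Sec-Pro arrays lay apart from the other 6.

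**Figure D1:**
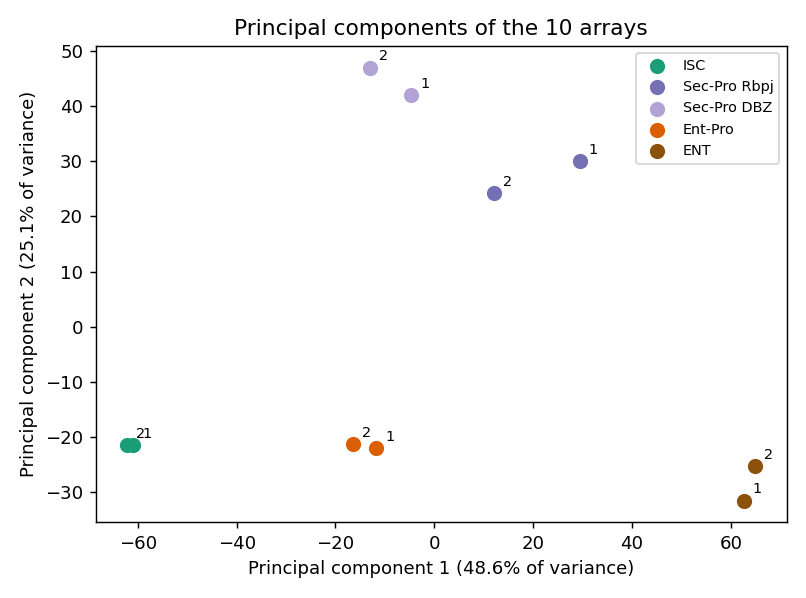
First against second principal component of the log2 values of all genes, 1 point per array, coloured by group and labelled by replicate. The first axis (48.6% of the variance) runs from the 2 ISC arrays to the 2 ENT arrays, and the second (25.1%) sets the 4 Sec-Pro arrays above the others.

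The genes targeted in the mice were read first. Atoh1, the transcription factor required for secretory cells, read 5.75 and 5.78 (log2) in Ent-Pro and 4.97 and 5.18 in ENT, the groups from Atoh1-null mice, against 7.68 and 7.80 in ISC, 10.40 and 10.78 in Rbpj Sec-Pro and 11.80 and 11.85 in DBZ Sec-Pro. Rbpj, the DNA-binding partner of activated Notch, read 6.74 and 6.62 in Rbpj Sec-Pro, where it was deleted, and 8.26 and 8.31 in DBZ Sec-Pro, where it was not, a difference of 1.61 (SE 0.12, adjusted p = 0.00059). It also read 7.003 and 7.213 in ENT, and 8.07 to 8.22 in ISC and Ent-Pro. The labels do not give the deleted part of either gene, so whether the probe sets lie inside it is open.

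Sec-Pro against Ent-Pro sets the secretory against the absorptive branch within the crypt. Goblet cell genes differed most: Clca1, a protein of goblet cell mucus, was at least 369-fold higher in Sec-Pro (13.19 ± 0.36, SD, n = 4, against 4.07 ± 0.18, SD, n = 2, near background; measured log2 fold change 9.12, SE 0.21, adjusted p = 5.3e-08). Zg16, a lectin of the mucus layer, was 302-fold higher and Tff3, a trefoil peptide secreted with mucins, 204-fold higher. Neurog3, which starts enteroendocrine differentiation, was 119-fold higher (12.18 ± 1.10, SD, n = 4, against 5.28 ± 0.02, SD, n = 2; adjusted p = 6.5e-07), and Atoh1 itself 43.6-fold higher (SE 0.13 on the log2 scale, adjusted p = 5.3e-08). The Ent-Pro mice lack Atoh1, so a difference in that gene is set by the design. The labels also describe these mice as lacking secretory cells, so the direction for goblet and enteroendocrine genes was largely set by it too. The other genes among the 8 largest increases, from 6.80 to 9.12 on the log2 scale as measured, were Rnase1, Selenom and the chemokines Ccl6 and Ccl9. Dmbt1, a secreted scavenger receptor of epithelia, was 17.2-fold lower (9.73 ± 1.89, SD, n = 4, against 13.84 ± 0.39, SD, n = 2; adjusted p = 0.00069). The other largest decreases, from -2.86 to -2.36, were Gm6958, Fgfbp1, Coq8a, the glutamate transporter Slc1a1, the water channel Aqp4, the nuclear receptor Nr5a2 and Mpzl2.

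All the lists of secretory cell types were higher in Sec-Pro. For goblet, Paneth and enteroendocrine genes this direction was largely set by the design, since the labels describe the Ent-Pro mice as lacking secretory cells. Of 15 goblet genes measured, 14 rose and 1 did not pass (14 adjusted over the list alone; median log2 fold change 4.77, camera adjusted p = 8.5e-23, adjusted p = 0.18 with an estimated correlation). Of 25 enteroendocrine genes, 23 rose (24 adjusted over the list alone). Among them were Tac1, which encodes the precursor of substance P (45.7-fold), and Chga, a protein of hormone granules (12.3-fold; adjusted p = 9.8e-06). The list median was 3.31 (adjusted p = 3.9e-27, adjusted p = 0.18 with an estimated correlation). Of 7 Paneth genes, 6 rose (6 adjusted over the list alone), led by the lectin Itln1 (38.5-fold) and the antibacterial phospholipase Pla2g2a (30.1-fold). Lysozyme, Lyz1, was at least 19.8-fold higher (15.03 ± 0.02, SD, n = 4, at the top of the scale, against 10.73 ± 0.60, SD, n = 2; adjusted p = 0.0024). The Paneth list had an adjusted p of 1.6e-06, and an adjusted p = 0.23 with an estimated correlation. Of 11 tuft cell genes 7 rose (9 adjusted over the list alone). The cytoskeletal regulator Avil was 8.26-fold and Alox5ap, of leukotriene synthesis, 6.25-fold higher (list adjusted p = 1.7e-05, adjusted p = 0.35 with an estimated correlation). Tuft genes were not even over the Sec-Pro arrays: the list mean was 6.18 on Rbpj replicate 1 and 7.61 to 7.98 on the others. Of 16 secretory regulators 13 rose (14 adjusted over the list alone), Neurog3 and the goblet and Paneth cell factor Spdef (51.8-fold) the most (adjusted p = 2.5e-18, adjusted p = 0.18 with an estimated correlation). That list includes Atoh1, which the Ent-Pro mice lack.

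Genes of protein folding in the endoplasmic reticulum also rose: 17 of 21 (19 adjusted over the list alone), led by the stress sensor of mucus cells Ern2 (14.0-fold) and Edem1, of glycoprotein degradation (3.08-fold; list adjusted p = 1.0e-12, adjusted p = 0.25 with an estimated correlation). Of 30 cell cycle genes 26 fell and 0 rose (29 lower adjusted over the list alone; median -0.85, adjusted p = 4.6e-10, adjusted p = 0.28 with an estimated correlation). They included Tyms, which makes thymidylate (at least 1.43-fold lower, near background in Sec-Pro), and the replication helicase subunit Mcm3 (2.16-fold lower). The proliferation marker Mki67 was 1.90-fold lower (adjusted p = 0.042). Of 13 Notch genes 5 fell (5 adjusted over the list alone), with the receptor Notch2 4.43-fold and the Notch target Hes1 3.63-fold lower. Rbpj, itself deleted in Rbpj Sec-Pro, is counted among those that fell. The Notch list had an adjusted p of 0.047 and an adjusted p = 0.26 with an estimated correlation. Its call was lost without ISC replicate 1 or 2, DBZ replicate 2 or ENT replicate 1 or 2 (adjusted p from 0.050 to 0.062), with arrays centred on their medians and with the mean of the probe sets.

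Smaller shifts were seen in other lists. Of 15 brush border genes 6 rose (9 adjusted over the list alone; median 0.50, adjusted p = 6.2e-06, adjusted p = 0.29 with an estimated correlation). Those with the largest changes were enteropeptidase, Tmprss15 (2.86-fold, with overlapping arrays, 7.94 and 7.87 in Rbpj and 5.05 and 4.96 in DBZ), and the protease Mep1a (2.55-fold; 0.75 on the log2 scale without Ent-Pro replicate 2). With both Sec-Pro groups pooled, 5 of 21 xenobiotic genes rose (5 adjusted over the list alone; median 0.28, adjusted p = 0.00094, adjusted p = 0.49 with an estimated correlation). Largest were the cytochromes Cyp2c55 (4.45-fold) and Cyp1a1 (4.30-fold; 7.28 ± 3.18, SD, n = 4, with overlapping arrays and a log2 fold change of -0.53 in DBZ alone). The list means were 11.28 and 11.45 in Rbpj, but 10.20 and 9.575 in DBZ against 10.39 and 9.59 in Ent-Pro, and Gsta4 too was -0.45 in DBZ alone. The pooled median was 0.46 without Rbpj replicate 1, 0.14 without DBZ replicate 1, 0.61 without Ent-Pro replicate 1 and -0.01 (adjusted p = 0.059) without Ent-Pro replicate 2. Of 15 immediate-early genes 4 rose (5 adjusted over the list alone), Btg2 3.40-fold and Dusp1 3.13-fold (median 0.41, adjusted p = 0.0023, adjusted p = 0.31 with an estimated correlation). The median was 0.37 (adjusted p = 0.0998) without Ent-Pro replicate 1, 0.65 without Ent-Pro replicate 2 and 0.22 without Rbpj replicate 1. Of 23 leukocyte markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), led by the pan-leukocyte phosphatase Ptprc (7.12-fold) and the T-cell receptor subunit Cd3g (5.27-fold). The leukocyte list had a median of 0.68, an adjusted p of 0.00081 and an adjusted p = 0.54 with an estimated correlation. Its call was lost among genes above the median level, and its median was 0.41 without Rbpj replicate 1, 1.19 without Rbpj replicate 2 and 1.07 without DBZ replicate 1.

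The other lists did not pass between Sec-Pro and Ent-Pro. Higher and lower members numbered 4 and 8 of 22 stem cell markers (4 and 9 adjusted over the list alone), 3 and 4 of 15 Wnt targets (4 and 4), 1 and 1 of 21 lipid genes (1 and 1), 2 and 2 of 16 transporters (2 and 2) and 2 and 9 of 20 enterocyte transcription factors (2 and 9). They numbered 2 and 6 of 24 chromatin genes (2 and 7), 1 and 4 of 20 stromal markers (1 and 4), 2 and 2 of 10 pancreatic genes (2 and 3) and 0 and 0 of 6 MHC class II genes (0 and 0). For Wnt targets the median (-0.13) was below 0 and the camera direction up, for pancreatic genes the median (0.01) was above 0 and the direction down, and for stromal markers the median was -0.17 and the mean 0.03. Lgr5, the stem cell receptor, differed by 0.29 (SE 0.52, adjusted p = 0.72), and by -0.29 without Rbpj replicate 2. Fabp1 and Apoa1, of lipid uptake and lipoproteins, differed by 0.11 (adjusted p = 0.47) and 0.27 (adjusted p = 0.24), with signs that turned in DBZ alone. Rbpj was lower by a log2 fold change of -0.63 (adjusted p = 0.0045), with overlapping arrays, a value of 0.17 in DBZ alone and 0.05 for its dimmest probe set.

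In all, 1149 genes were higher and 1826 lower in Sec-Pro than in Ent-Pro, 2975 together. Of the 685 that changed at least 2-fold, more were higher (465) than lower (220), and tested against a 2-fold change 153 were higher and 17 lower. The split depended on scaling, with 1001 higher and 2504 lower after centring arrays on their medians and 1434 higher and 1206 lower after cyclic loess. Without Ent-Pro replicate 1 there were 911 calls, without Ent-Pro replicate 2 903, and with the 4 Sec-Pro arrays as 1 group 1530. Without 1 of the Ent-Pro arrays the calls of Alox5ap, Aqp4, Avil, Gm6958, Mep1a, Tmprss15, Tyms, Rbpj, Mki67, Cd3g and Cyp1a1 were lost (adjusted p from 0.059 to 0.223), all with their sign kept. The call of Mki67 was also lost without either ISC or either DBZ array (0.052 to 0.101), that of Cyp1a1 without either DBZ array (0.053 and 0.055), and that of Cd3g without either ISC array, either ENT array or DBZ replicate 2 (0.054 to 0.094).

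**Figure D2:**
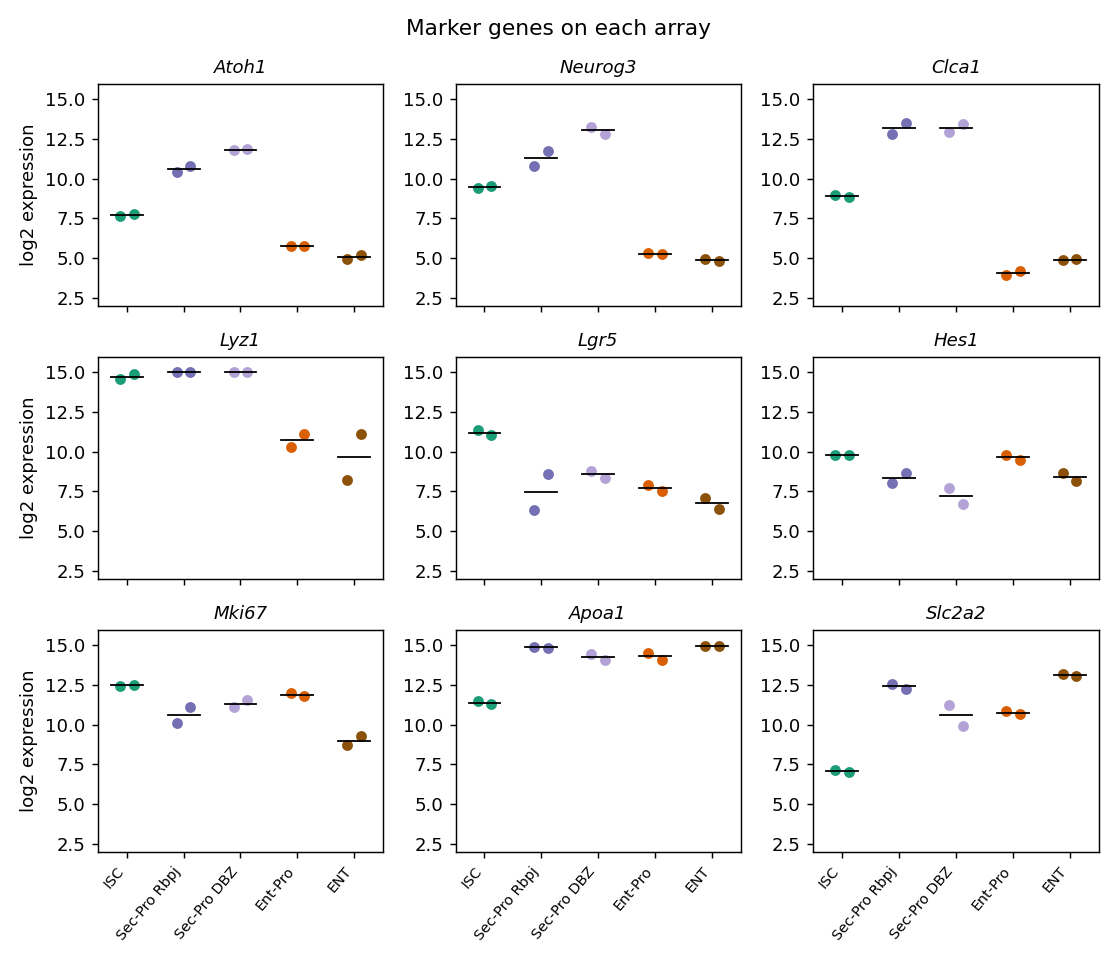
Log2 expression of 9 genes on each of the 10 arrays, 1 point per array, with a line at each group mean. Atoh1, Neurog3 and Clca1 are highest in the 2 Sec-Pro groups (Clca1 13.19 in Sec-Pro against 4.07 in Ent-Pro), Lgr5 is highest in ISC (11.21), and Apoa1 is higher in every other group than in ISC (11.40).

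Both ways of blocking Notch were also set against Ent-Pro separately. DBZ Sec-Pro had 1096 genes higher and 1211 lower, and Rbpj Sec-Pro 1161 and 2094. Of these, 532 were higher in both, 679 lower in both and 25 went opposite ways. Independent lists of these sizes would share 102.7 and 204.6 genes, a figure that does not allow for the shared Ent-Pro arrays. Across genes, the log2 fold changes correlated with r = 0.705, against 0.499 in 100 simulations of unchanged groups with the same Ent-Pro arrays. Their covariance was 0.332 against a simulated 0.0209, a difference of 0.311. With 1 Ent-Pro array on each side, so that no control array was shared, r was 0.630 and 0.679. Both sides still subtract the same Atoh1-null group, so whatever sets Ent-Pro apart enters both, and the simulated groups held no such effect. Neither the overlap nor r can therefore tell a shared effect of blocking Notch from a trait of Ent-Pro. The shared calls numbered 735 without DBZ replicate 2, 416 without Ent-Pro replicate 1 and 391 without Ent-Pro replicate 2, against 1211 in all, and were 469 higher and 1009 lower after centring.

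Sec-Pro against ISC sets secretory progenitors against the stem cells above them. Pmp22, a membrane protein of peripheral myelin and epithelia, was 59.8-fold higher in Sec-Pro (10.49 ± 0.54, SD, n = 4, against 4.59 ± 0.30, SD, n = 2; log2 fold change 5.90, SE 0.29, adjusted p = 7.1e-06). Sec24d, part of the coat of vesicles leaving the endoplasmic reticulum, was 25.6-fold higher (adjusted p = 4.2e-07), and the peptide transporter Slc15a1 27.3-fold higher. Lgr5 fell 9.11-fold (8.02 ± 1.16, SD, n = 4, against 11.21 ± 0.21, SD, n = 2; adjusted p = 0.0012). The other increases among the 8 largest, from 4.64 to 5.02, were S100a6, the hypoxia-regulated hydroxylase Egln3, Bst1, guanine deaminase Gda and Gzma, granzyme A of cytotoxic lymphocytes. The largest decreases, from -4.87 to -3.50 as measured, included the immediate-early factors Fosb, Egr1, Egr2 and Jun, together with Fstl1, the linker histone H1f4, Dmbt1 and endothelin, Edn1. Of these, Fosb and H1f4 were near background in Sec-Pro.

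Stem cell markers fell as a list, 18 of 22 (19 adjusted over the list alone) with 1 higher, led by Fstl1 (13.8-fold lower) and Lgr5 (adjusted p = 6.2e-05, adjusted p = 0.29 with an estimated correlation). Of 15 Wnt targets 8 fell (8 adjusted over the list alone), Lgr5 and the stem cell factor Ascl2 (4.31-fold lower) the most (median -1.10, adjusted p = 0.0093, adjusted p = 0.26 with an estimated correlation). Of 30 cell cycle genes 19 fell (19 adjusted over the list alone), with Mki67 2.86-fold and the kinetochore motor Cenpe 3.91-fold lower (adjusted p = 0.00079, adjusted p = 0.56 with an estimated correlation). Of 24 chromatin genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), among them Uhrf1 and Dnmt3a of DNA methylation (3.22-fold and 2.88-fold lower; median -0.47, adjusted p = 0.023, adjusted p = 0.60 with an estimated correlation). The chromatin call was lost without Rbpj replicate 1 (adjusted p = 0.056) and among genes above the median level.

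Secretory lists rose from ISC to Sec-Pro as well. Goblet genes rose in 13 of 15 cases (14 adjusted over the list alone), led by Clca1 (19.5-fold) and Ccl9 (14.0-fold; list adjusted p = 1.3e-09, adjusted p = 0.25 with an estimated correlation). Enteroendocrine genes rose in 19 of 25 (21 adjusted over the list alone), with neurotensin, Nts, near background in ISC, at least 9.30-fold, the factor Insm1 9.71-fold and Chga 2.51-fold higher (adjusted p = 1.4e-09, adjusted p = 0.25 with an estimated correlation). Secretory regulators rose in 14 of 16 (14 adjusted over the list alone), Gfi1 12.7-fold and Atoh1 11.1-fold (adjusted p = 1.3e-09, adjusted p = 0.23 with an estimated correlation). Folding genes of the endoplasmic reticulum rose in 19 of 21 and fell in 2 (19 and 2 adjusted over the list alone), led by Sdf2l1 (5.46-fold) and Edem1 (4.19-fold; list adjusted p = 5.2e-09, adjusted p = 0.26 with an estimated correlation). Of 7 Paneth genes 3 rose (3 adjusted over the list alone), Pla2g2a 8.97-fold and the protease Mmp7 5.48-fold. Lyz1 read 14.73 in ISC, itself close to the highest values of those arrays, and lay at the top of the scale in Sec-Pro. Its difference of 0.30 (adjusted p = 0.72) therefore does not show that it was unchanged. The Paneth list had an adjusted p of 0.039 and an adjusted p = 0.30 with an estimated correlation. Its call was lost without ISC replicate 1 (0.094) or Rbpj replicate 2 (0.065), after centring or loess and among genes above the median level. Of 11 tuft genes 6 rose (6 adjusted over the list alone), led by the kinase Dclk1 (5.12-fold) and Hpgds, of prostaglandin synthesis (at least 3.47-fold, near background in ISC), both with overlapping arrays. The tuft list had a median of 1.47, an adjusted p of 0.012 and an adjusted p = 0.61 with an estimated correlation. Its median was 0.89 without ISC replicate 2 and 0.87 without Rbpj replicate 2, and its call was lost among genes above the median level.

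Absorptive genes were higher in Sec-Pro too. Unlike ISC, the Sec-Pro crypts were not sorted, so enterocytes among them cannot be told apart from secretory progenitors that express these genes. The transporter list mean was 10.39 and 10.16 in Rbpj and 9.49 and 8.88 in DBZ, against 7.68 and 7.53 in ISC. All 15 brush border genes rose (15 adjusted over the list alone), with the proteases Mep1b (14.6-fold) and Enpep (11.5-fold) in front (median 1.81, adjusted p = 4.5e-11, adjusted p = 0.25 with an estimated correlation). Lipid genes rose in 17 of 21 (17 higher and 1 lower adjusted over the list alone). The apolipoproteins rose, Apoc2 12.9-fold, Apoc3 10.97-fold and Apoa1 9.09-fold and the fatty acid carrier Fabp1 4.61-fold (adjusted p = 9.2e-10, adjusted p = 0.27 with an estimated correlation). Transporters rose in 13 of 16 and fell in 1 (13 and 1 adjusted over the list alone), with the glucose carrier Slc2a2 21.9-fold higher (adjusted p = 2.1e-07, adjusted p = 0.25 with an estimated correlation). Xenobiotic genes rose in 19 of 21 (19 adjusted over the list alone), led by the cytochromes Cyp3a13 (17.5-fold) and Cyp3a11 (14.9-fold; list adjusted p = 4.6e-10, adjusted p = 0.26 with an estimated correlation).

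Notch genes did not pass as a list, though 7 of 13 fell (7 adjusted over the list alone), among them Notch1 (4.37-fold lower) and Hes1 (4.07-fold lower; list adjusted p = 0.080). Of 20 enterocyte transcription factors 6 rose and 11 fell (6 and 11 adjusted over the list alone). Higher and lower members numbered 2 and 3 of 20 stromal markers (0 and 0 adjusted over the list alone), 0 and 2 of 10 pancreatic genes (0 and 2) and 0 and 1 of 6 MHC class II genes (0 and 1). The stromal median was -0.10, with a mean of 0.12 and an upward camera direction. Rbpj, deleted in Rbpj Sec-Pro, is counted among the Notch genes that fell. It differed by -0.70 (adjusted p = 0.00079), with overlapping arrays, a value of 0.10 in DBZ alone and 0.31 for its dimmest probe set.

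The sort and the RNA of ISC differed from the other groups in ways that bear on both comparisons with ISC. Leukocyte markers rose in 12 of 23 cases from ISC to Sec-Pro and fell in 2 (12 and 2 adjusted over the list alone), with Gzma 25.0-fold and Ptprc, near background in ISC, at least 17.9-fold higher (median 1.47, adjusted p = 0.00036, adjusted p = 0.51 with an estimated correlation). The median was 0.96 without Rbpj replicate 1, and the call was lost among genes above the median level. Ptprc read 4.40 and 4.56 in ISC, which were sorted by fluorescence, and 6.06 or more on every other array. Immediate-early genes fell in 12 of 15 cases (13 adjusted over the list alone), with Fosb at least 21.5-fold and Egr1 19.5-fold lower in Sec-Pro (median -2.07, adjusted p = 1.4e-06, adjusted p = 0.25 with an estimated correlation). The 3' minus 5' difference of the Actb control, a sign of RNA integrity and labelling, was 1.92 and 2.02 (log2) on the ISC arrays and 0.45 to 1.01 on the others, and that of Gapdh 1.61 and 1.81 against -0.02 to 0.32. ISC also read high for products of Paneth and goblet cells, with Lyz1 at 14.73, Spink4 at 13.61, Tff3 at 13.35 and Itln1 at 12.66. Whether the stem cells themselves made them was not tested.

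Between Sec-Pro and ISC, 2230 genes were higher and 3376 lower in Sec-Pro, 5606 together. Of the 1959 that changed at least 2-fold, 1057 were higher and 902 lower. Cyclic loess gave 2838 higher and 2519 lower and moved the median of all genes from -0.11 to 0.02. The call of Mmp7 was lost without ISC replicate 1 (adjusted p = 0.122) and that of Hpgds without ISC replicate 1 or 2 (0.063 and 0.059). The call of Dclk1 was lost without any 1 array of the ISC, DBZ, Ent-Pro or ENT groups (0.062 to 0.264). Its log2 fold change was 2.36, 1.41 without Rbpj replicate 2 and -0.32 for its dimmest probe set.

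Ent-Pro against ISC sets enterocyte progenitors against stem cells. Pmp22 was again the most increased, 51.5-fold (10.27 ± 0.41 against 4.59 ± 0.30, SD, n = 2 each; adjusted p = 3.4e-05). Krt20, a keratin of differentiated epithelium, was 19.0-fold higher (adjusted p = 4.9e-05) and adenosine deaminase, Ada, 18.7-fold higher. The single genes that fell most were goblet products: Zg16 was 88.5-fold lower (5.45 ± 0.0011 against 11.92 ± 0.21, SD, n = 2 each, log2 fold change -6.47, SE 0.25, adjusted p = 4.0e-06) and Tff3 81.6-fold lower. The other largest increases, from 3.93 to 4.77, were the ectoenzyme Enpp3, the sialyltransferase St3gal4, Slc15a1, Cyp3a13 and Emp1. Among the largest decreases, from -6.47 to -4.89, were also the goblet cell genes Spink4 and Fcgbp, the chemokine Ccl6, the stress protein Nupr1, and Egr1 and Dusp1.

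The goblet, enteroendocrine, Paneth and secretory regulator lists fell in Ent-Pro, while the tuft list did not pass. The Ent-Pro mice lack Atoh1 and, per the labels, secretory cells, so low secretory genes in Ent-Pro were largely set by the design. Of 15 goblet genes 11 fell (12 adjusted over the list alone; adjusted p = 4.6e-10, adjusted p = 0.25 with an estimated correlation). Of 25 enteroendocrine genes 16 fell (16 adjusted over the list alone), Neurog3 18.7-fold, Tac1 10.8-fold and Chga 4.89-fold (adjusted p = 4.1e-10, adjusted p = 0.25 with an estimated correlation). Of 7 Paneth genes 4 fell (4 adjusted over the list alone), Nupr1 29.7-fold and Lyz1 from 14.73 to 10.73 (adjusted p = 0.012, adjusted p = 0.27 with an estimated correlation). Of 16 secretory regulators 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Spdef 5.05-fold and Atoh1 3.94-fold lower (adjusted p = 0.00036, adjusted p = 0.27 with an estimated correlation). Stem cell markers fell in 10 of 22 cases (10 adjusted over the list alone), led by Lgr5 (11.1-fold lower) and Tnfrsf19 (8.72-fold lower; list adjusted p = 0.00017, adjusted p = 0.30 with an estimated correlation). Of 15 Wnt targets 6 fell (6 lower and 1 higher adjusted over the list alone), Lgr5 and the guidance receptor Ephb3 (5.44-fold lower) the most. The Wnt median was -0.47 (adjusted p = 0.0093, adjusted p = 0.26 with an estimated correlation), and -0.71 without ISC replicate 2.

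Absorptive lists rose. Brush border genes were higher in 12 of 15 cases (12 adjusted over the list alone), Enpep 12.3-fold and Mep1b 8.95-fold (adjusted p = 1.6e-08, adjusted p = 0.26 with an estimated correlation). Lipid genes were higher in 16 of 21 and lower in 1 (16 and 1 adjusted over the list alone). Leading were Apoa4 (9.17-fold) and Mttp, which loads lipid onto lipoproteins (8.28-fold), with Apoa1 7.52-fold and Fabp1 4.26-fold higher (adjusted p = 1.8e-09, adjusted p = 0.27 with an estimated correlation). Transporters were higher in 13 of 16 (13 adjusted over the list alone), Slc15a1 20.5-fold and Slc2a2 12.9-fold (adjusted p = 1.4e-09, adjusted p = 0.25 with an estimated correlation). Xenobiotic genes were higher in 13 of 21 (13 adjusted over the list alone), Cyp3a13 16.5-fold and Cyp2b10 11.3-fold (adjusted p = 1.3e-07, adjusted p = 0.28 with an estimated correlation). Of 21 folding genes 6 rose and 3 fell (6 and 3 adjusted over the list alone), and those with the largest changes fell: Ern2 7.45-fold and Ddit3, a factor of stress-induced cell death, 3.32-fold. That list had a median of 0.39, an adjusted p of 0.019 and an adjusted p = 0.61 with an estimated correlation. Its call was lost without ISC replicate 1 (0.070) or Ent-Pro replicate 2 (0.186), after loess and among genes above the median level.

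Immediate-early genes fell in 12 of 15 cases here too (12 adjusted over the list alone), Egr1 45.9-fold and Dusp1 33.5-fold (median -2.28, adjusted p = 4.6e-12, adjusted p = 0.23 with an estimated correlation), with a median of -3.66 without Ent-Pro replicate 2. Only ISC had been sorted, and its 3' minus 5' differences stood apart as given for Sec-Pro. The high readings of Paneth and goblet products in ISC, also given there, bear on the secretory lists here too. Higher and lower members of lists that did not pass numbered 0 and 0 of 11 tuft genes (0 and 0 adjusted over the list alone), 1 and 2 of 13 Notch genes (1 and 2), 5 and 1 of 30 cell cycle genes (5 and 1), 5 and 3 of 20 enterocyte transcription factors (5 and 3) and 1 and 5 of 24 chromatin genes (1 and 5). They numbered 2 and 1 of 23 leukocyte markers (2 and 1), 1 and 0 of 20 stromal markers (1 and 0), 1 and 1 of 10 pancreatic genes (1 and 0) and 0 and 0 of 6 MHC class II genes (0 and 0). Mki67 differed by -0.59 (adjusted p = 0.23), Hes1 by -0.17 (adjusted p = 0.78) and Rbpj by -0.07 (adjusted p = 0.76), the last with its sign turned under every other scaling.

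Altogether 1498 genes were higher and 1667 lower in Ent-Pro than in ISC, 3165 together, 1101 of them at least 2-fold (555 higher and 546 lower). Centring arrays on their medians gave 1905 higher and 1277 lower and moved the median of all genes from -0.02 to 0.10. There were 1817 calls without ISC replicate 2, 1816 without Ent-Pro replicate 1 and 1704 without Ent-Pro replicate 2.

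ENT against Ent-Pro follows enterocytes from crypt to villus in Atoh1-null mice. S100g, the calcium-binding protein of calcium uptake, was 54.3-fold higher in ENT (13.29 ± 0.46 against 7.53 ± 1.99, SD, n = 2 each; log2 fold change 5.76, SE 0.91, adjusted p = 0.0011). Slc40a1, the iron exporter ferroportin, was 30.8-fold higher (adjusted p = 0.00015), and Car2, a carbonic anhydrase, 25.3-fold higher. Hells, a chromatin remodeller of dividing cells, was 11.6-fold lower (7.53 ± 0.61 against 11.07 ± 0.09, SD, n = 2 each; adjusted p = 8.3e-05), Bub1, of the mitotic checkpoint, 8.11-fold lower, and Mki67 7.49-fold lower (adjusted p = 0.00019). The other largest increases, from 4.65 to 5.51, were fibronectin, Fn1, the complement regulator Cd55, Siglecf, malic enzyme, Me1, and the interferon-induced protease Usp18. The other largest decreases, from -4.05 to -2.94, were Ceacam10, Gm6958, the DNA polymerase subunit Pola1, Gsdme, the condensin subunit Smc2 and Rif1.

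All 30 cell cycle genes fell (30 adjusted over the list alone; median -2.01, adjusted p = 3.5e-17, adjusted p = 0.25 with an estimated correlation). Chromatin genes fell in 13 of 24 cases and rose in 2 (17 and 2 adjusted over the list alone), with Hells and the maintenance methyltransferase Dnmt1 (4.45-fold) lowest (adjusted p = 3.4e-05, adjusted p = 0.30 with an estimated correlation). Stem cell markers fell in 15 of 22 and rose in 2 (15 and 2 adjusted over the list alone), led by Aqp4 (7.02-fold) and Igfbp4 (5.31-fold; list adjusted p = 0.00017, adjusted p = 0.30 with an estimated correlation). Wnt targets fell in 7 of 15 and rose in 2 (7 and 2 adjusted over the list alone), with cyclin D1, Ccnd1, 6.25-fold and Ascl2 5.25-fold lower (adjusted p = 0.023, adjusted p = 0.27 with an estimated correlation). Secretory regulators fell in 7 of 16 (7 adjusted over the list alone). The members with the largest changes, Foxa3 (4.33-fold lower) and Sox4 (4.13-fold lower), also act outside the secretory lineage. That list had an adjusted p of 0.038 and an adjusted p = 0.43 with an estimated correlation. It lost its call without ENT replicate 2 (0.063), after loess and among genes above the median level. Atoh1 itself was 1.61-fold lower (adjusted p = 0.0059) and counts among the members that fell. Its readings were low, 5.07 in ENT and 5.76 in Ent-Pro. Both groups come from mice without Atoh1, so this is a difference in residual signal.

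Digestive and absorptive genes rose further. Brush border genes were higher in 13 of 15 cases (13 adjusted over the list alone), with Tmprss15 6.76-fold and trehalase, Treh, 4.29-fold higher (adjusted p = 4.5e-07, adjusted p = 0.27 with an estimated correlation). Lipid genes were higher in 16 of 21 (18 adjusted over the list alone), led by the lipoprotein receptor Scarb1 (10.2-fold) and the fatty acid receptor Cd36 (4.71-fold). The lipid median was 1.09 (adjusted p = 1.8e-06, adjusted p = 0.32 with an estimated correlation), and 0.70 without ENT replicate 2. Transporters were higher in 12 of 16 (12 adjusted over the list alone), with the sulfate carrier Slc13a1 12.8-fold higher (adjusted p = 6.2e-06, adjusted p = 0.26 with an estimated correlation). Xenobiotic genes were higher in 16 of 21 (16 adjusted over the list alone), Cyp1a1 23.1-fold and Cyp2c29 19.4-fold (adjusted p = 5.9e-07, adjusted p = 0.29 with an estimated correlation). Of 20 enterocyte transcription factors 11 rose and 1 fell (12 and 2 adjusted over the list alone), with Klf4 4.90-fold and Prdm1 4.34-fold higher (adjusted p = 0.00093, adjusted p = 0.23 with an estimated correlation).

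Tuft cell genes rose in 10 of 11 cases (11 adjusted over the list alone), among them Siglecf (31.7-fold) and Alox5ap (16.7-fold; list median 2.38, adjusted p = 0.00011, adjusted p = 0.40 with an estimated correlation). The labels describe the Atoh1-null mice as lacking secretory cells. Goblet, Paneth and enteroendocrine lists did not pass, with higher and lower members numbering 2 and 1 of 15 (0 and 0 adjusted over the list alone), 0 and 0 of 7 (0 and 0) and 1 and 3 of 25 (1 and 3). Immediate-early genes rose in 10 of 15 cases and fell in 1 (11 and 1 adjusted over the list alone), with Atf3 5.22-fold and Zfp36 4.07-fold higher (adjusted p = 0.00012, adjusted p = 0.27 with an estimated correlation). Villi and crypts had been in EDTA for 25 and 50 min. Leukocyte markers numbered 7 higher and 2 lower of 23 (7 and 2 adjusted over the list alone; list adjusted p = 0.075), with Gzmb, granzyme B, 7.30-fold higher. Higher and lower members numbered 1 and 4 of 13 Notch genes (1 and 5 adjusted over the list alone), 6 and 9 of 21 folding genes (6 and 10), 0 and 0 of 20 stromal markers (0 and 0), 2 and 1 of 10 pancreatic genes (1 and 1) and 0 and 1 of 6 MHC class II genes (0 and 0), and none of these lists passed. Mean MHC class II expression was 10.03 on ENT replicate 1 and 7.75 on ENT replicate 2.

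In total 2291 genes were higher and 2501 lower in ENT than in Ent-Pro, 4792 together, 2219 of them at least 2-fold (997 higher and 1222 lower). Centring gave 2974 higher and 2128 lower and moved the median of all genes from 0.02 to 0.15. The call of Fabp1 (log2 fold change 0.39) was lost without any 1 of the 4 arrays compared (adjusted p from 0.103 to 0.146). Those of Apoa1 (0.68) and Cd36 (2.24) were lost without Ent-Pro replicate 2 or either ENT array (0.060 to 0.140), and that of Hes1 (-1.22) without Ent-Pro replicate 1 (0.095) or ENT replicate 2 (0.110). Lgr5 differed by -0.99 (adjusted p = 0.25), Chga by -0.48 (adjusted p = 0.14) and Lyz1 by -1.07 (adjusted p = 0.30), the last by 0.38 without ENT replicate 1. Rbpj was 2.01-fold lower in ENT (adjusted p = 0.00031).

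**Figure D3:**
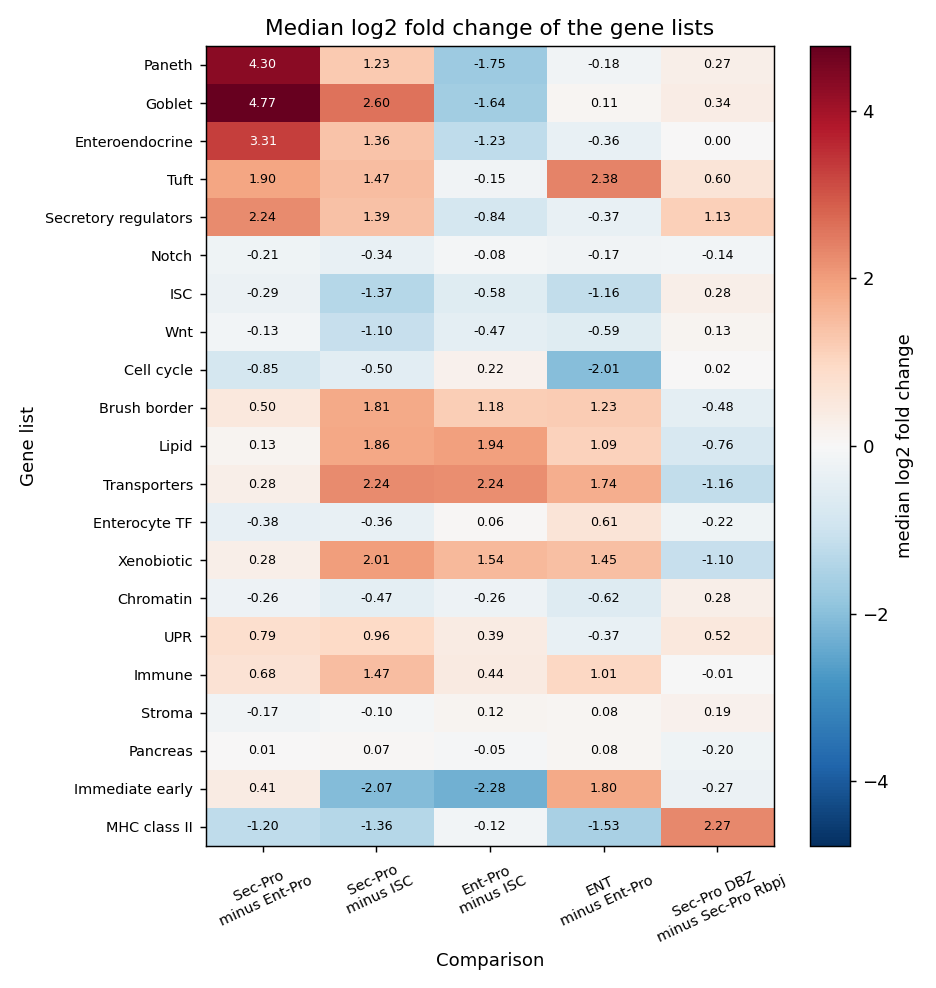
Heat map of the median log2 fold change of the 21 gene lists (down the side) in the 5 comparisons (across the map), on the log2 scale, with the value printed in each field. Goblet genes read 4.77 in Sec-Pro against Ent-Pro and -1.64 in Ent-Pro against ISC, and cell cycle genes -2.01 in ENT against Ent-Pro.

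DBZ against Rbpj Sec-Pro sets both ways of blocking Notch against each other. The largest increase in DBZ was Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus, at least 23.9-fold (9.23 ± 0.06 against 3.69 ± 0.02, SD, n = 2 each, near background in Rbpj; measured log2 fold change 5.54, SE 0.15, adjusted p = 1.1e-06). Bhlha15, a factor of secretory cell maturation, was 6.08-fold higher (adjusted p = 0.0049), Neurog3 3.41-fold and Atoh1 2.34-fold (11.82 ± 0.04 against 10.59 ± 0.27, SD, n = 2 each; adjusted p = 0.0032). Among the largest decreases in DBZ were the absorptive genes S100g, 51.5-fold lower (6.65 ± 1.39 against 12.34 ± 0.95, SD, n = 2 each, adjusted p = 0.0075), and Slc40a1, 15.16-fold lower. Hes1 was 2.23-fold lower in DBZ (adjusted p = 0.045). The other largest increases, from 2.53 to 3.13, were Cbx6, the cytochrome Cyp2e1, the immunoglobulin segment Igkv8-30, Tceal8, Thbs1 and Epb42. The other largest decreases, from -5.27 to -3.72 as measured, were Cyp1a1 and Anxa10, both near background in DBZ, Abhd1, the interferon-induced Ifit1, Bbox1, of carnitine synthesis, and the glutathione transferase Gsta2.

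Secretory regulators rose in 11 of 16 cases (16 adjusted over the list alone; median 1.13, adjusted p = 1.6e-08, adjusted p = 0.23 with an estimated correlation), led by Bhlha15 and Neurog3. Folding genes rose in 9 of 21 and fell in 1 (12 and 2 adjusted over the list alone), Ern2 2.82-fold and the disulfide isomerase Pdia6 2.28-fold (-0.36 on the log2 scale for its dimmest probe set). Their median was 0.52 (adjusted p = 0.00037, adjusted p = 0.40 with an estimated correlation), and 0.28 without DBZ replicate 2. Chromatin genes rose in 3 of 24 (7 adjusted over the list alone), with the demethylases Kdm1a 2.08-fold and Kdm5b 1.78-fold higher (median 0.28, adjusted p = 0.012, adjusted p = 0.55 with an estimated correlation). The median was 0.21 without Rbpj replicate 1, with the call lost (0.359), and 0.45 without Rbpj replicate 2.

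Xenobiotic genes fell in 10 of 21 cases (13 adjusted over the list alone), led by Cyp1a1 (at least 36.7-fold between group means) and Gsta4 (12.9-fold). Cyp1a1 was uneven in Rbpj, at 11.05 on replicate 1 and 8.78 on replicate 2. The xenobiotic list had a median of -1.10 (adjusted p = 2.1e-10, adjusted p = 0.26 with an estimated correlation). Transporters fell in 9 of 16 (12 lower and 1 higher adjusted over the list alone), Slc40a1 and Slc13a1 (4.93-fold) the most (median -1.16, adjusted p = 4.3e-07, adjusted p = 0.26 with an estimated correlation). Lipid genes fell in 10 of 21 and rose in 1 (14 and 1 adjusted over the list alone), with Dgat2, of triglyceride synthesis, 5.72-fold and Apoc2 4.84-fold lower (median -0.76, adjusted p = 5.0e-08, adjusted p = 0.29 with an estimated correlation). Brush border genes fell in 2 of 15 (3 adjusted over the list alone), Tmprss15 7.49-fold and Treh 2.16-fold. The brush border median was -0.48 (adjusted p = 0.00038, adjusted p = 0.38 with an estimated correlation), -0.24 without Rbpj replicate 1 and -0.32 without DBZ replicate 2. Enterocyte transcription factors fell in 5 of 20 and rose in 1 (6 and 1 adjusted over the list alone), with the nuclear receptors Nr1i3 3.29-fold and Pparg 3.07-fold lower. Their median was -0.22 (adjusted p = 0.0041, adjusted p = 0.25 with an estimated correlation), -0.14 without Rbpj replicate 1, -0.34 without DBZ replicate 1 and -0.07 without DBZ replicate 2. Fabp1 was 1.38-fold lower (adjusted p = 0.037).

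Lists of cell types did not pass. Higher and lower members numbered 1 and 0 of 7 Paneth genes (1 and 0 adjusted over the list alone), 4 and 1 of 15 goblet genes (5 and 1), 7 and 2 of 25 enteroendocrine genes (9 and 4), 0 and 0 of 11 tuft genes (0 and 0) and 5 and 2 of 22 stem cell markers (6 and 2). They numbered 2 and 2 of 13 Notch genes (4 and 3), 2 and 1 of 15 Wnt targets (2 and 1), 0 and 1 of 30 cell cycle genes (0 and 0), 1 and 1 of 15 immediate-early genes (2 and 2) and 1 and 1 of 23 leukocyte markers (1 and 1). They numbered 3 and 0 of 20 stromal markers (3 and 0), 0 and 3 of 10 pancreatic genes (1 and 4) and 0 and 0 of 6 MHC class II genes (0 and 0), whose mean was 10.44 on Rbpj replicate 1 and 6.14 on Rbpj replicate 2. The cell cycle median was 0.02, with a mean of -0.001 and a downward camera direction, and the leukocyte median was -0.01 with a mean of 0.09. The Notch genes counted as higher in DBZ include Rbpj, which was deleted in the other group. Lgr5 differed by 1.13 (adjusted p = 0.23), and by -0.03 without Rbpj replicate 1. Mki67 differed by 0.70 (adjusted p = 0.16), Chga by 0.74 (adjusted p = 0.057) and Apoa1 by -0.60 (adjusted p = 0.056). Lyz1 lay at the top of the scale in both groups, so its difference of -0.03 (adjusted p = 0.98; 0 after quantile normalization) says nothing about a change.

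In this comparison 1158 genes were higher and 878 lower in DBZ, 2036 together. The excess of higher genes was absent after cyclic loess (1036 higher and 1033 lower) and quantile normalization (1030 and 1030), and among the 594 that changed at least 2-fold (275 and 319). The count was 1018 without Rbpj replicate 1, 1273 without DBZ replicate 1, 363 without DBZ replicate 2, 957 with array weights, 1167 among genes above the median level and 97 in a fit of these 4 arrays alone. Hybridisation control BioB read 10.15 and 10.03 on the Rbpj arrays and 7.81 and 6.64 on the DBZ arrays. It read 8.45 and 8.84 in ISC, 7.44 and 7.61 in Ent-Pro and 6.52 and 6.30 in ENT. If groups were hybridised apart, that cannot be told apart from group in any of the comparisons. The 3' minus 5' difference of Actb was 1.01 on DBZ replicate 2, against 0.58 on DBZ replicate 1 and 0.49 and 0.59 on the Rbpj arrays, and that of Gapdh 0.32 against -0.02, -0.01 and 0.03. Whether RNA quality bears on the calls that rest on DBZ replicate 2 was not tested. Without DBZ replicate 2 the calls of Anxa10, Apoc2, Ern2, Ifit1, Kdm1a, Slc13a1, Tceal8, Treh, Hes1 and Fabp1 were lost (adjusted p from 0.051 to 0.241), with signs kept. Those of Anxa10 (0.078) and Slc13a1 (0.059) were also lost without DBZ replicate 1, that of Slc13a1 without Rbpj replicate 2 (0.077) and that of Apoc2 without Rbpj replicate 1 (0.053), where Anxa10 was -2.06 against -3.72. The calls of Hes1 and Fabp1 were further lost without any array of the ISC, Ent-Pro or ENT groups (0.052 to 0.072), and without Rbpj replicate 2 (0.133) and Rbpj replicate 1 (0.122) respectively.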

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

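The tests of villus cells, of a deviating array, of leukocytes, of signal loss and of crypt against villus origin were chosen after the results they measure had been seen; those of RNA quality and of the Rosa26 neighbours were not. Of 30 values tested over the 4 Sec-Pro arrays, 2 had 1 array standing far from the others, where chance gives about 1 in 20; taking those arrays together, across both ways of blocking Notch, was also decided after the data had been seen. Mean expression of the stem cell list was 8.02 (log2) on Rbpj replicate 1 and 8.67 to 8.73 on the other 3, and mean MHC class II expression was 6.14 on Rbpj replicate 2 and 10.21 to 10.44 on the other 3. Between the Sec-Pro groups, tested as DBZ against Rbpj, median log2 differences passed for secretory regulators (1.13), folding genes (0.52), chromatin genes (0.28), brush border (-0.48), lipid (-0.76), transporter (-1.16) and xenobiotic genes (-1.10) and enterocyte transcription factors (-0.22) at the preset correlation. With an estimated correlation 0 of 105 list tests passed (smallest adjusted p = 0.176), and the chromatin call was also lost without Rbpj replicate 1 (adjusted p = 0.359). Among the genes fixed for every group, Atoh1 (1.23), Rbpj (1.61), Hes1 (-1.16) and Fabp1 (-0.46) differed too.

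Part of the enterocyte list genes lay lower in DBZ than in Rbpj Sec-Pro. A candidate explanation is villus enterocytes in the Rbpj preparations, which no sort would have removed. Of 31 members of the enterocyte lists called lower in DBZ, 27 of them above 8 in Ent-Pro crypts too and 0 on a second list, all 31 were higher in ENT than in DBZ, with a median implied villus share of 51.8% (quartiles 34.9 and 89.8%), and 2, Gstm1 and Abcb1a, exceeded ENT in the Rbpj group by more than 2 SE (by 0.41 and 1.28, 6.45% of members); the abundant Apoa1 read 14.89 in Rbpj, 14.28 in DBZ and 14.99 in ENT. These members were picked for being called lower in DBZ, and the others were left out, so the implied share leans high. As genes of enterocyte lists they were also likely to be higher in ENT whatever the cause. The share of 51.8% predicts a cell cycle shift of -0.467 in Rbpj, which is too large if the share is too high. The median over 30 genes was -0.0178. The SE of the mean was 0.0599, taken over genes, which are not independent replicates. The bound set for this test wrongly assumed that crypt cells of both groups cycle alike. Rbpj replicates 1 and 2 lay at -0.233 and 0.266 relative to DBZ, so a mixture cannot be told apart from a difference between the crypt cells. A single deviating Rbpj array as the whole cause is argued against by the 4 enterocyte lists (brush border, lipid, transporter, xenobiotic), of which 4 passed without Rbpj replicate 1 and 4 without replicate 2, at the preset correlation only (0 with an estimated one, smallest adjusted p = 0.176); without Rbpj replicate 1 the medians were -0.24 (brush border, from -0.48), -0.55, -0.90 and -1.41, so that array may hold part of the brush border difference. The difference between deleting Rbpj and inhibiting Notch, which the design names, stays open and untested.

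MHC class II genes were low on Rbpj replicate 2 (6.14) and on ENT replicate 2 (7.75), against 10.28 (SD 0.200) on the 6 other arrays outside ISC. Fewer leukocytes are argued against on ENT replicate 2, where the median of 23 leukocyte genes, 0 of them on another list, differed from replicate 1 by 0.101 (SE over genes 0.0890) while MHC class II differed by -2.51. The abundant Gzma and Ccl5 read 12.04 and 11.17 on replicate 1 and 12.38 and 11.30 on replicate 2. On Rbpj replicate 2 the leukocyte median was lower too, by a difference of -1.75 (SE over genes 0.210), with Gzma at 11.05 against 13.25. Fewer leukocytes as the whole cause are argued against there, since MHC class II differed by -4.81, or -3.06 (SE over genes 0.782) beyond the leukocyte genes. All 4 arrays with a lower leukocyte mean than the 6.49 of Rbpj replicate 2, those of Ent-Pro and sorted ISC (5.65 to 6.33), read 10.18 to 10.64 for MHC class II. The SEs are over genes within a pair of arrays, not over samples. A general loss of signal could not be judged from genes of the same level, whose median replicate differences were 0.0511 (7856 genes, Rbpj) and -0.0404 (8317 genes, ENT). These make up most of the 12393 genes, and the arrays were already on a common scale, which keeps such a median small. A part of leukocytes in the Rbpj difference stays open; what sets these arrays apart may be a difference between animals or housing, which the labels do not give, and no biological explanation was tested.

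Gt(ROSA)26Sor read near the floor on the 4 Rbpj Sec-Pro and Ent-Pro arrays, with a measured difference of -4.92 from the other 6. Crypt against villus origin is argued against by DBZ Sec-Pro, also from crypts, which lay 5.33 (SE 0.154, adjusted p = 2.4e-07) above Ent-Pro. Of 4125 genes above 8 on the other 6 arrays, 1 was under 4.5 on those 4, Gt(ROSA)26Sor itself. This argues against poor RNA or hybridisation that cost many bright genes their signal. A milder fault would not reach these bounds, and the common scale of the arrays would hide one that met all genes alike. Such faults could not be judged. The 10 measured neighbours on chromosome 6 had a median difference of -0.181 (-0.393 to 0.562), as an altered Rosa26 locus in those mice, a common site of inserted transgenes, would give. Regulation of this transcript alone would give it too. Some neighbours, such as Cav3 (4.78) and Oxtr (4.87), were dim on the other 6 arrays and had little room to fall. Others, such as Thumpd3 (8.82) and Brpf1 (8.83), were not. An altered locus remains a hypothesis that the labels do not settle: they give no genotype at Rosa26, and ENT, with the same Atoh1 genotype as Ent-Pro, lay 4.32 above it (adjusted p = 8.0e-06).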

How the results depend on the processing

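Leaving out the 2 arrays with low MHC class II was chosen after the data had been seen; all other alternatives were planned. Over these settings together, apart from those that leave out a single array, 5596 values of named genes kept direction and side of the threshold, 549 lost their call, 41 gained one and 43 changed sign; list calls were kept in 347 cases and lost in 73, 60 of these with an estimated correlation, where 0 lists passed. Without 1 array, 4043 gene values were kept, 380 lost their call, 23 gained one and 4 changed sign, and list calls were kept in 586 cases and lost in 14. Alternatives for single lists were run only where the list passed. A floor of 64 on linear values was not run, since the values are log2. The number of arrays and, for genes near the absent control, signal over background limit all results.

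For Sec-Pro against Ent-Pro, Sec-Pro against ISC, Ent-Pro against ISC, ENT against Ent-Pro and DBZ against Rbpj, calls at least 2-fold numbered 685, 1959, 1101, 2219 and 594, and calls tested against a 2-fold change 170, 580, 164, 608 and 19, by construction fewer. With the replicate number as a block, calls were 2617, 5377, 2981, 4608 and 1713, the overlap against Ent-Pro 1085 and lists 60. Replicate differences correlated across genes with r from -0.19 to 0.17 over 10 pairs of groups, 1 above 0.1 and 2 below -0.1. Over all genes this gave little sign of pairing. The labels do not say whether replicate numbers pair samples, so a shared origin that affects some genes stays open. Leaving out 1 array gave 903 to 3714, 3954 to 5953, 1704 to 3656, 3319 to 5220 and 363 to 2742 calls, an overlap of 391 to 1480 and 58 to 70 lists. Without both MHC-low arrays there were 3810, 6009, 3763, 4433 and 2817 calls, an overlap of 1516 and 71 lists. The 4 Sec-Pro arrays as 1 group gave 1530 calls against Ent-Pro, where their difference counts as spread. DBZ against Rbpj gave 1167 calls among genes above the median level and 97 with only the 4 arrays compared, from fewer genes and fewer arrays, and 957 with array weights; the cause was not tested.

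Some named genes changed sign (log2 fold changes; the cause was not tested). With the dimmest probe set these were, in Sec-Pro against Ent-Pro, Cpe (-0.41), Jag1 (0.070), Rbpj (0.054) and Tnfrsf19 (-0.27), and against ISC Dclk1 (-0.32) and Rbpj (0.31). In Ent-Pro against ISC they were Acta2 (-0.36), Bhlha15 (0.13), Jag1 (-0.28), Kdm5b (0.19) and Rbpj (0.26). In ENT against Ent-Pro they were Cela3b (-0.41), Clca1 (-0.034), Cpe (-0.29), Isl1 (0.11), Notch2 (0.32), Pdgfrb (-0.89), Pdia6 (0.30) and Top2a (0.22). In DBZ against Rbpj they were Hyou1 (-0.51), Lfng (-0.16), Lyz1 (0.13, at the top of the scale), Msi1 (-0.48), Pdia6 (-0.36) and Prss2 (0.074). The mean of probe sets turned Rbpj in Ent-Pro against ISC (0.094), Pdgfrb in ENT (-0.27) and Lyz1 in DBZ against Rbpj (0.054). Rbpj in Ent-Pro against ISC was also 0.050 after centring, 0.10 after loess and 0.030 after quantile normalization, which set Lyz1 in DBZ against Rbpj to 0. With DBZ alone as Sec-Pro, values against Ent-Pro were -0.029 for Apoa1, -0.53 for Cyp1a1, -0.12 for Fabp1, -0.45 for Gsta4, 0.17 for Rbpj, -0.033 for Slc2a5 and -0.43 for Slc40a1, and against ISC 0.10 for Rbpj; with Rbpj Sec-Pro alone, Lgr5 was -0.27 against Ent-Pro. Without 1 array, Lgr5 ranged from -0.29 to 0.86 in Sec-Pro against Ent-Pro and from -0.026 to 2.28 in DBZ against Rbpj, Lyz1 from -2.51 to 0.38 in ENT against Ent-Pro, and H2-Ab1 from -0.26 to 4.87 in DBZ against Rbpj. Without both MHC-low arrays Lgr5 was -0.29 in Sec-Pro against Ent-Pro and H2-Ab1 -0.26 in DBZ against Rbpj.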

Other observations

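The values given here were chosen after the data had been seen, and none of them was tested further. Ifit1, which binds viral RNA, read 10.35 and 10.15 (log2) in Rbpj Sec-Pro and 7.51 and 10.08 in ENT, against 4.67 and 4.75 in ISC, 6.32 and 5.95 in DBZ Sec-Pro and 6.22 and 6.32 in Ent-Pro. Irf7, a factor of the interferon response, read 10.04 and 8.88 in Rbpj Sec-Pro, 9.08 and 9.62 in ENT and 7.30 to 7.90 elsewhere. Igha, the constant region of immunoglobulin A, read 6.61 and 6.33 in ISC and 8.48 to 11.39 on the other arrays.

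Dclk1, a kinase of tuft cells, read 9.26 on Rbpj replicate 2 and 5.49 on Rbpj replicate 1, 8.17 and 8.23 in DBZ Sec-Pro, 9.55 and 8.81 in ENT, 5.69 and 4.99 in Ent-Pro and 5.92 and 4.93 in ISC. Siglecf read 8.96 and 5.65 on the same Rbpj arrays, 8.40 and 7.42 in DBZ Sec-Pro, 10.50 and 9.46 in ENT, 5.20 and 4.78 in Ent-Pro and 6.32 and 5.47 in ISC.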
